A study of Mus musculus with 8 samples.

How the data were processed

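Transcript levels were measured in leukaemic spleen cells of 4 mice carrying acute myeloid leukaemia driven by MLL-AF10, a fusion gene that joins the histone methyltransferase gene MLL to AF10. Per the labels, the leukaemias had been started from c-kit-positive bone marrow cells that were immortalised by retroviral transduction and transplanted into syngeneic mice given sub-lethal irradiation. Spleen cells of each mouse were separated by flow sorting on surface c-kit (CD117) into a c-kit-high fraction, called CD117pos here, and a fraction with little or no c-kit, called CD117neg. Each fraction of each mouse gave 1 array, so that 4 CD117pos and 4 CD117neg arrays were compared. The array titles end in _948, _951, _952 and _953, and the mice are called by these endings. Replicates are therefore separate animals, but whether the 4 leukaemias came from separate transductions is not given in the sources used here.

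Per the labels' protocols, polyA RNA was purified on columns, its quality was checked by capillary electrophoresis, and it was amplified in 2 cycles and labelled with biotin for Affymetrix arrays of 1 colour. The deposited values were an intensity on a linear scale for each of 45101 probe sets on each array. The software that summarised probes into probe sets and the scaling between arrays are not given in the sources used here. In the deposited intensities, array medians lay between 27.5 and 32.8 and upper quartiles between 181 and 220.8. The columns were thus close to each other without sharing 1 distribution, and they were used as deposited. Between 841 and 898 values per array were exactly 1, as after a floor, so differences between very low intensities carry no information. Detection calls were not analysed here. Arrays have no read depth, and the number of arrays limits the precision.

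Probe sets were named from the platform's annotation table. Of the probe sets, 34958 had 1 gene symbol, some controls among them. Among those other than controls, 932 had several and 9160 had none listed, and these 10092 were not named here. The gene identifiers of 34754 matched a current mouse gene table, which changed 0 symbols. The 64 control probe sets were left out of the tests. Each of the 18193 named genes was represented by its probe set with the highest mean over the 8 arrays. Of 9010 genes with several probe sets, 20 had probe sets past the threshold in opposite directions. No genomic coordinates are printed, because the sources used here name no genome build for the array design.

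Intensities were transformed as log2(intensity + 16), which understates the change of genes with low signal. All differences are CD117pos minus CD117neg on this scale, and folds are computed from them. The difference was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), with the mouse as a block, over all 8 arrays. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The mouse terms of the same fit were tested with a moderated F-test. Means are given ± SD over 4 arrays and log2 differences ± SE. Control measures of the arrays were compared with exact permutation tests, in which the fractions were exchanged within mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

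The block follows from the design text, by which each mouse gave both fractions. As a check on this pairing, each array's deviation from its fraction's mean was correlated across genes between the fractions. The correlation within a mouse was 0.21, 0.22, 0.27 and 0.12 for mice _948, _951, _952 and _953. The highest correlation with an array of another mouse was 0.03, -0.01, 0.11 and 0.11 in the same order. Genes are not independent replicates in these correlations.

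Before the data were examined, 34 gene lists with 1002 genes were fixed, of which 897 genes were measured. One held Kit alone. The other 33 were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. They covered genes made prominent by work on MLL leukaemia stem cells, targets of MLL fusions, stem and progenitor regulators, DNA replication, mitosis, ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, heterochromatin, polycomb and trithorax factors, glycolysis and cholesterol synthesis. Further lists covered monocyte and macrophage maturation, primary granule proteins, late neutrophil genes, MHC class II presentation, interferon-stimulated genes, cytokines, lysosome, p53 targets and apoptosis, myeloid transcription factors and immediate early genes. The remaining lists held markers of 9 other cell types that a sorted spleen fraction may hold, and sex-linked genes. Genes named in the text follow a rule set at the same time: Kit, the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in all 4 mice, up to 3 members of each list with the largest change past the threshold (or the member with the largest difference where none passed), all members of the stem cell list, and the 5 genes with the largest F between mice. Other genes are marked where they appear as chosen after their values were seen.

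Alternatives set beforehand were the fit without the block, quantile normalisation, centring of each array on its median, pseudocounts of 1 and 64, leaving out the lowest 40% of genes by mean, the mean of all probe sets of a gene, leaving out probe sets with shared sequence (suffixes _x_at and _s_at), an intensity trend and a robust prior in eBayes, a minimum change of 2-fold, leaving out each mouse in turn, and for lists an estimated correlation in camera and limma's fry. An alternative without the CD117pos array of mouse _951 was added after seeing the data. The fit was tested on simulated data for the same comparison with 18193 genes, of which 50 were changed at each of 4 sizes. It recovered 64% of genes changed 2-fold, 90% of those changed 4-fold, 96% at 8-fold and 98% at 16-fold, and 4.92% of its calls were false. The changed genes were drawn from those with a mean above the median of all genes, and the change was added on the log2 scale. These rates thus do not cover genes of low signal, or data with as many calls as here. With no change simulated, 0 of 33 lists were called, and a list shifted by 0.5 on the log2 scale was called with 0 others. The simulated noise was independent between genes, while the correlation estimated in the data was 0.815 for mitosis. The simulation therefore does not show how often camera calls a list by error here. At the preset correlation, camera's p does not measure the spread of a list between mice. With an estimated one, camera rests on 3 residual degrees of freedom and has little power.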

Results

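The study compared c-kit-high with c-kit-negative cells of the same leukaemic spleens. In mouse leukaemias driven by MLL fusion genes, cells able to start the disease on transplantation are known to be more frequent among c-kit-high cells, and the comparison asks which transcripts set this fraction apart. The 4 mice, whose array titles end in _948, _951, _952 and _953, each gave 1 CD117pos and 1 CD117neg array, 8 arrays in all. Each array held 45101 probe sets, and 18193 named genes were tested. Array medians were 31.8 ± 0.873 (SD, n = 4) in the CD117neg arrays and 28.8 ± 1.60 in the CD117pos arrays. Correlations of log2 intensities between arrays of 1 fraction were 0.982 to 0.991 among CD117neg arrays and 0.929 to 0.989 among CD117pos arrays. Below, a pair of means ± SD gives the intensity in the CD117neg and then the CD117pos fraction, each over 4 mice.

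Kit encodes the surface receptor used for the sort and serves to check the labels. Its intensity was 28.6 ± 9.73 in the CD117neg and 751 ± 127 in the CD117pos arrays (Entrez gene 16590), higher in all 4 mice. The log2 difference was 4.12 ± 0.14 (limma, adjusted p = 0.000138). Being the sorted marker, it is no finding.

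Among calls of at least 2-fold, falls outnumbered rises in CD117pos cells, by 1331 to 403 in the intensities as deposited, 1084 to 729 after quantile normalisation and 1171 to 570 after centring. The calcium-binding protein gene S100a6 (Entrez gene 20200) went from 4137 ± 680 to 22.0 ± 13.8, a log2 difference of -6.83 ± 0.22. Ahnak, encoding a large scaffold protein, differed by -6.41 ± 0.19, and Slfn1, a Schlafen family gene, by -6.29 ± 0.22. Mmp8, the neutrophil collagenase, differed by -6.06 ± 0.18. The other genes among the 10 largest falls were Adamdec1, Dusp16, Klf4, Lpl, Bst1 and Sirpb1a, with log2 differences between -6.01 and -5.82. All 10 ended at CD117pos means below the median of those arrays, so that the sizes and order of these falls depend on the pseudocount. With pseudocounts of 1 and 64, S100a6 differed by -7.70 and -5.61, Ahnak by -7.55 and -5.08 and Slfn1 by -7.40 and -4.95. Among rises, Far2 (Entrez gene 330450), a fatty acyl-CoA reductase gene, went from 93.1 ± 33.1 to 1587 ± 351, a log2 difference of 3.90 ± 0.18. Nkg7, a granule membrane protein gene, rose by 3.53 ± 0.36, Dio2, the type 2 iodothyronine deiodinase gene, by 2.83 ± 0.26, and Afap1, an actin filament-associated protein gene, by 2.77 ± 0.13. Gprasp2, Rnase10, Elane, Tuba8 and Abhd14a followed with log2 differences between 2.67 and 2.29. The CD117neg mean of Gprasp2 lay below the median of those arrays, and its difference was 3.51 and 1.75 with pseudocounts of 1 and 64. Adjusted p among these 20 genes, Kit included, lay between 0.000138 (S100a6) and 0.01 (Tuba8). With the mean of all probe sets of a gene, the difference was -1.70 for Ahnak, -2.55 for Slfn1, 1.52 for Dio2 and 1.01 for Afap1, and without probe sets of shared sequence it was 0.88 for Abhd14a, all past the threshold. The Tuba8 call ended without mouse _948 (adjusted p = 0.0601) and without mouse _952 (0.0511). Its difference there was 2.2 and 2.36, against 2.32 over all mice.

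In all, 1521 genes were higher and 2518 lower in CD117pos (limma, adjusted p under 0.05), and 4035 of these 4039 genes moved the same way in all 4 mice. A test of differences within 4 mice favours genes with a shared direction, so this agreement is no separate evidence. Higher genes made up 37.7% of the calls in the intensities as deposited, 55.7% after quantile normalisation (2439 higher, 1941 lower) and 48.4% after centring on array medians (1958 higher, 2084 lower), so which direction held more genes depended on the scaling. Leaving out a mouse moved the counts to 450 higher and 1230 lower (mouse _948), 2130 and 2985 (mouse _951), 611 and 1404 (mouse _952) and 440 and 1219 (mouse _953). Without the CD117pos array of mouse _951, in a fit without the block that was chosen after seeing the data, 2167 genes were higher and 2955 lower.

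**Figure D1:**
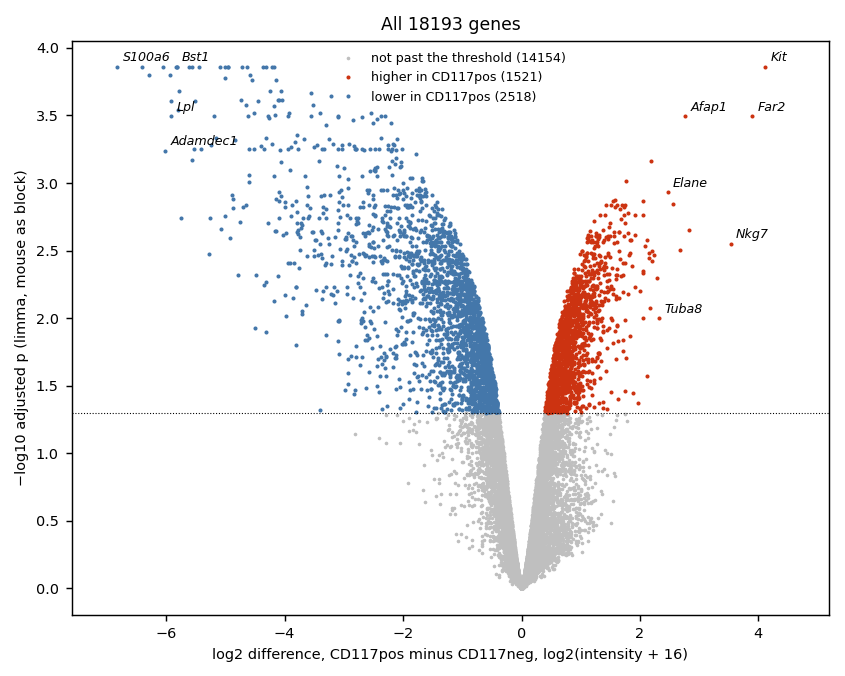
Each point is 1 of 18193 genes, with the log2 difference (CD117pos minus CD117neg, log2(intensity + 16)) on the x axis and the negative log10 of the limma adjusted p on the y axis. The dotted line marks an adjusted p of 0.05, red points are the 1521 higher genes and blue points the 2518 lower ones, and the falls reach -6.83 (S100a6) while the rises reach 4.12 (Kit).

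Most listed genes of mature monocytes and macrophages were lower in CD117pos cells. Of 49 measured members of that list, 37 fell and 0 rose (42 fell when adjusted over the list alone), with a median log2 difference of -2.43. Klf4, a transcription factor of monocyte differentiation, went from 2265 ± 934 to 19.9 ± 12.4. Lgals3, encoding galectin-3, went from 5565 ± 338 to 118 ± 91.0, and Clec4n, the dectin-2 gene, from 2491 ± 1110 to 46.4 ± 32.1. The list's camera adjusted p was 1.74e-17, with adjusted p = 0.206 under an estimated correlation. Of 28 transcription factors of myeloid differentiation, 17 fell and 1 rose (21 and 2 when adjusted over the list alone), with a median of -1.23. The median was -1.74 in mouse _951, against -1.25 to -1.02 in the other mice. Nr4a1 differed by -4.84 ± 0.25, Irf5 by -4.07 ± 0.15 and Klf2 by -2.89 ± 0.27. That list's camera adjusted p was 2.13e-08, and its adjusted p = 0.206 with an estimated correlation. Of 13 genes of MHC class II presentation, 7 fell and 0 rose (8 and 0 when adjusted over the list alone), with a median of -2.22. The cathepsin gene Ctss went from 7532 ± 710 to 282 ± 213, the invariant chain gene Cd74 from 861 ± 363 to 32.1 ± 10.3 and the costimulatory ligand gene Cd86 from 317 ± 122 to 6.16 ± 1.11. The median of the MHC class II list was -0.71 in mouse _951, against -2.28 to -1.60 in the other mice. Camera gave an adjusted p of 0.000108 for it, and adjusted p = 0.206 with an estimated correlation.

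Late neutrophil genes mostly fell and more primary granule genes rose than fell, but the 2 lists were not tested against each other. Late neutrophil genes, which encode contents of secondary and tertiary granules and surface receptors, fell in 21 of 26 cases and rose in 0 (22 and 0 when adjusted over the list alone), with a median of -2.54. Besides Mmp8, the gelatinase gene Mmp9 went from 6510 ± 1158 to 106 ± 49.5 and the chemokine receptor gene Cxcr2 from 1245 ± 425 to 11.4 ± 13.4. Camera gave an adjusted p of 1.76e-12, and adjusted p = 0.286 with an estimated correlation. The list's median in mouse _951 was -3.73, against -2.15 to -1.95 in the other mice. Primary granule proteins, made at the promyelocyte stage, rose in 7 of 12 cases and fell in 1 (the same counts when adjusted over the list alone), with a median of 0.89. The 1 fall became 0 with a pseudocount of 1 and without probe sets of shared sequence. Without mouse _948, 6 rose and 0 fell. Elane, encoding neutrophil elastase, went from 1010 ± 411 to 5416 ± 773, Nkg7 from 51.1 ± 68.0 to 910 ± 974, and Cst7, the cystatin F gene, from 293 ± 120 to 1425 ± 526. This list had a camera adjusted p of 0.000343, and adjusted p = 0.357 with an estimated correlation.

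**Figure D2:**
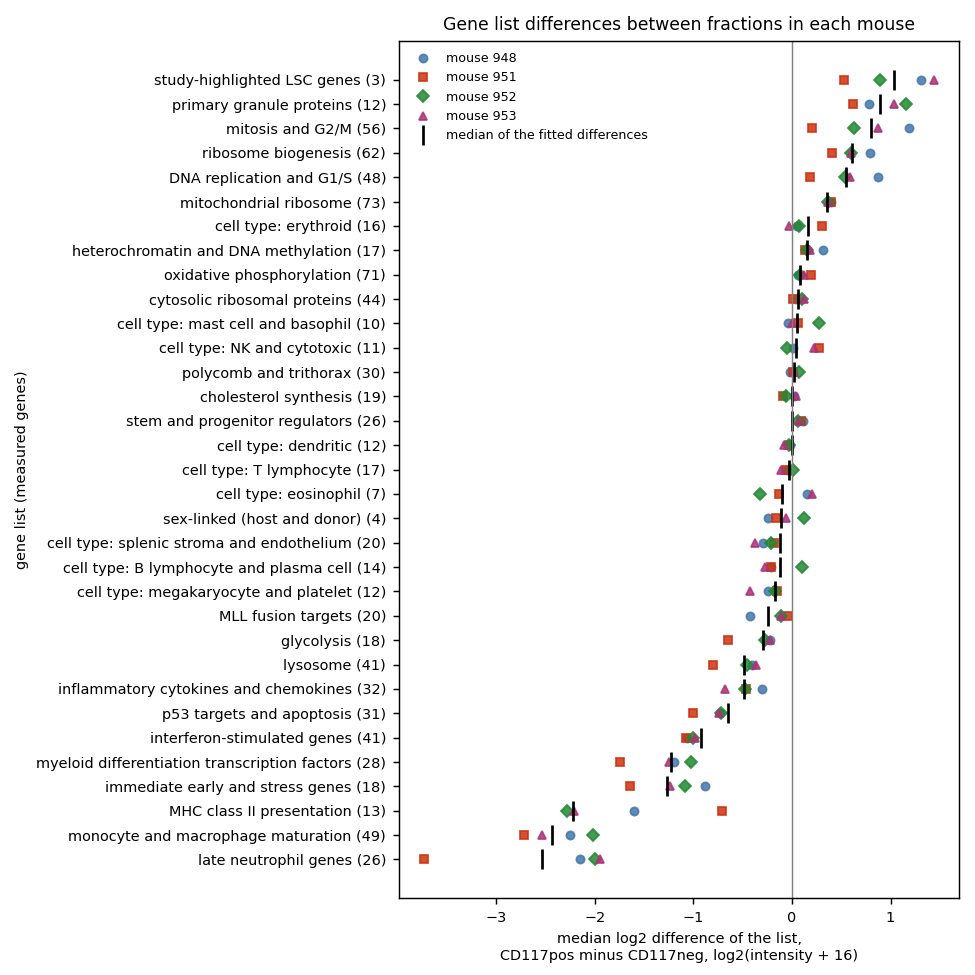
For each of 33 gene lists, with the number of measured genes in brackets, coloured symbols give the median log2 difference (CD117pos minus CD117neg) in each of the 4 mice, and the black bar the median of the fitted differences. Late neutrophil genes (-2.54) and genes of monocyte and macrophage maturation (-2.43) lie at the low end, and the stem cell list (1.04), primary granule proteins (0.89) and mitosis (0.80) at the high end.

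Many listed genes of cell division and of ribosome assembly were higher in CD117pos cells, by modest amounts, while 28 members of each of the 3 lists did not pass. Of 56 genes of mitosis and G2/M, 28 rose and 0 fell (38 and 0 when adjusted over the list alone), with a median of 0.80. The phosphatase gene Cdc25c went from 56.4 ± 14.8 to 196 ± 83.0, the ubiquitin-conjugating enzyme gene Ube2c from 269 ± 52.2 to 781 ± 138 and the centromere protein gene Cenph from 89.7 ± 26.6 to 273 ± 77.2. Camera gave an adjusted p of 1.35e-15 at the preset correlation of 0.01, and adjusted p = 0.436 with a correlation estimated as 0.815. Of 48 genes of DNA replication and G1/S, 19 rose and 1 fell (24 and 1 when adjusted over the list alone), with a median of 0.55. The replication list had a camera adjusted p of 1e-10, and adjusted p = 0.422 with a correlation estimated as 0.522. Thymidine kinase, Tk1, went from 544 ± 101 to 1290 ± 294, while the gene that fell, the transcription factor gene E2f2, went from 2632 ± 148 to 298 ± 61.8. The medians of the mitosis and replication lists were 0.20 and 0.18 in mouse _951, whose CD117pos array stood apart from the other arrays, and 0.63 to 1.19 and 0.54 to 0.87 in the other mice. Of 62 genes of ribosome biogenesis, 34 rose and 0 fell (46 and 0 when adjusted over the list alone), with a median of 0.61. Wdr12 went from 879 ± 81.6 to 1908 ± 232 and Grwd1 from 262 ± 45.1 to 565 ± 52.3. Camera gave an adjusted p of 6.15e-16 for them, and adjusted p = 0.286 with an estimated correlation. Leaving out mice _948, _951, _952 and _953 in turn gave 9, 48, 14 and 6 rises for mitosis, 7, 33, 9 and 4 for replication and 8, 46, 9 and 9 for ribosome biogenesis, and 45 mitosis genes rose after quantile normalisation. The Tk1 call ended without mouse _953 (adjusted p = 0.0552).

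Mitochondrial ribosomal protein genes rose in 25 of 73 cases and fell in 0 (35 and 1 when adjusted over the list alone), with a median of 0.36, a camera adjusted p of 2.79e-10 and adjusted p = 0.206 with an estimated correlation. Mrpl50 went from 331 ± 62.7 to 708 ± 108. After quantile normalisation 45 of the mitochondrial ribosomal protein genes rose, with a pseudocount of 1 there were 9, and without mice _948, _951, _952 and _953 in turn 1, 29, 5 and 5. Of 71 genes of oxidative phosphorylation, 9 rose and 1 fell (2 and 0 when adjusted over the list alone), with a median of 0.08. Its camera adjusted p was 0.00377, against adjusted p = 0.526 with an estimated correlation and 0.0836 by fry. After quantile normalisation 22 of these genes rose and 0 fell, with a median of 0.29, after centring 14 rose, with a pseudocount of 1 there were 3, and without mice _948, _951, _952 and _953 in turn 1, 9, 1 and 0. Of 78 listed cytosolic ribosomal protein genes only 44 were measured, of which 3 rose (Rpl12, Rps6 and Rpl14) and 0 fell. The counts were the same when adjusted over the list alone, and the median was 0.06. The camera adjusted p lay at the threshold without passing it (0.05). It became 0.597 with an estimated correlation, 0.0759 with a pseudocount of 1, 0.111 without mouse _952 and 0.119 without mouse _953, but passed by fry (0.0352), after quantile normalisation (0.00678) or centring (0.0126), and under most other settings. The call of Rpl12 ended without mouse _948 (0.0684) and without _953 (0.0623), and that of Rps6 without _953 (0.0535) and with the mean of its probe sets (0.0508). Between 4 and 7 rose after quantile normalisation or centring, with a pseudocount of 64, with an intensity trend or without the block, and 1 without mouse _953. Of 18 glycolysis genes, 7 fell and 0 rose (7 and 1 when adjusted over the list alone), with a median of -0.29. The median was -0.12 after quantile normalisation and -0.19 both after centring and without mouse _951. In mouse _951 it was -0.65, against -0.27 to -0.22 in the other mice. The glucose transporter gene Slc2a3 went from 3670 ± 905 to 437 ± 161 (a call that ended without probe sets of shared sequence, with a difference of -0.64 against -3.05 and adjusted p = 0.0598) and the enolase gene Eno3 from 1268 ± 692 to 130 ± 42.3. The camera adjusted p of 0.0226 for glycolysis became adjusted p = 0.372 with an estimated correlation, 0.0551 after quantile normalisation, 0.0812 without low genes, 0.102 without probe sets of shared sequence, 0.0603 without mouse _951 and 0.0803 without the CD117pos array of mouse _951 and the block. Without mouse _948, 4 glycolysis genes fell. Of 19 genes of cholesterol synthesis, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.839). Without mouse _948, 1 rose and 1 fell, and without mouse _952 or _953, 0 rose and 1 fell. Msmo1 went from 614 ± 119 to 247 ± 50.7.

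Many listed genes of the interferon response, inflammation, stress and p53 were lower in CD117pos cells, while others did not pass and a few rose. Of 41 interferon-stimulated genes, 29 fell and 2 rose (30 and 2 when adjusted over the list alone), with a median of -0.92, a camera adjusted p of 8.04e-11 and adjusted p = 0.206 with an estimated correlation. Irf7, a transcription factor that induces interferon genes, went from 1200 ± 291 to 116 ± 51.8, and Ifi204 from 231 ± 138 to 5.49 ± 2.94. Of 32 inflammatory cytokine and chemokine genes, 15 fell and 1 rose (17 and 1 when adjusted over the list alone), with a median of -0.49. Cxcl2 went from 815 ± 583 to 11.6 ± 4.97 and Il1b from 759 ± 491 to 28.6 ± 5.70. Camera gave an adjusted p of 0.00111 for the cytokines, and adjusted p = 0.269 with an estimated correlation. Of 18 immediate early genes, 10 fell and 1 rose (11 and 3 when adjusted over the list alone), with a median of -1.27, a camera adjusted p of 0.00383 and adjusted p = 0.352 with an estimated correlation. The 1 rise became 0 without the block, with a pseudocount of 1 and without mouse _948, and 2 after quantile normalisation or centring. Dusp1 went from 2084 ± 446 to 289 ± 71.5 and Jun from 206 ± 79.3 to 24.6 ± 19.8. Of 31 p53 targets and apoptosis genes, 17 fell and 0 rose (17 and 1 when adjusted over the list alone), with a median of -0.65. The antiproliferative gene Btg2 went from 1331 ± 69.2 to 150 ± 59.3 and Trp53inp1 from 3249 ± 417 to 386 ± 146. Its camera adjusted p was 2.79e-05, and adjusted p = 0.215 with an estimated correlation. Of 41 lysosome genes, 19 fell and 2 rose (24 and 2 when adjusted over the list alone), with a median of -0.49, a camera adjusted p of 5.58e-06 and adjusted p = 0.286 with an estimated correlation. The protease gene Lgmn went from 118 ± 34.9 to 6.12 ± 1.46. In mouse _951 the medians of the lysosome and immediate early lists were -0.80 and -1.64, against -0.46 to -0.36 and -1.24 to -0.88 in the other mice. Leaving out mice _948, _951, _952 and _953 in turn left 9, 20, 9 and 10 falls and 1, 2, 1 and 1 rises among lysosome genes, and 11 p53 targets fell without mouse _953.

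**Figure D3:**
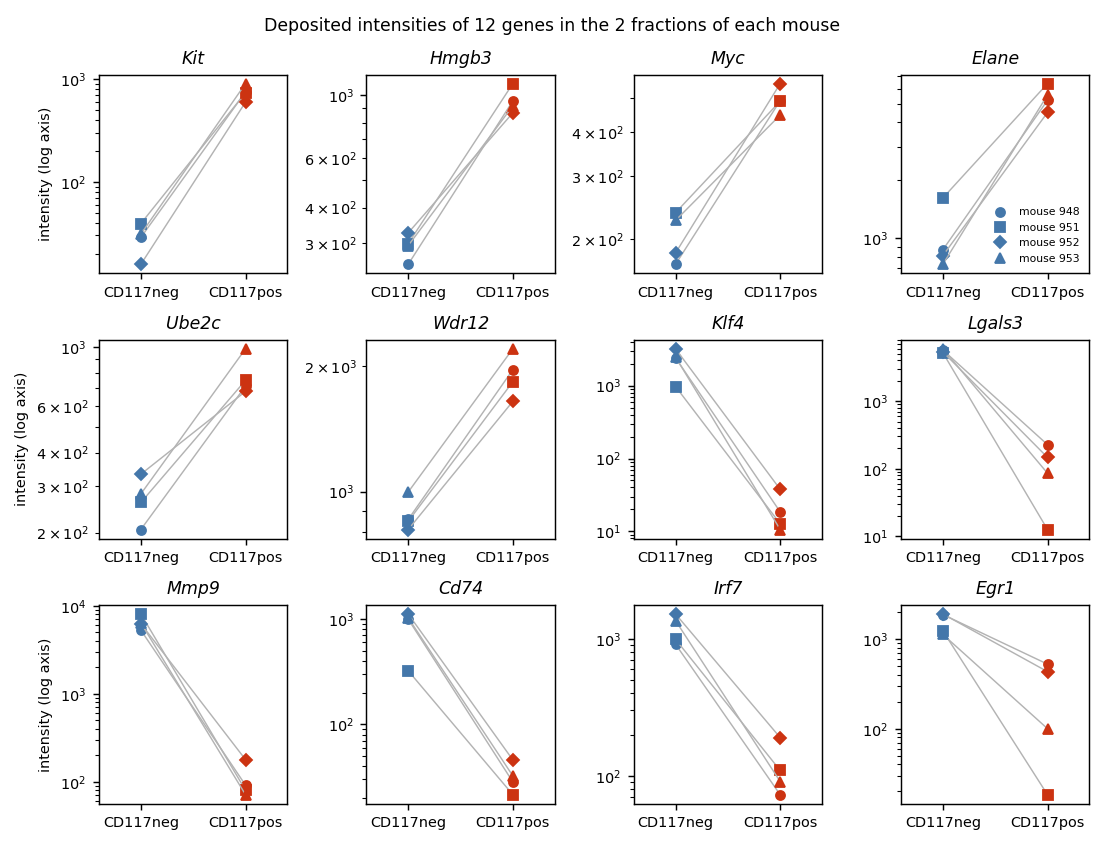
Deposited intensities (log axis) of 12 genes in the CD117neg (blue) and CD117pos (red) array of each mouse, joined by a line per mouse. All 12 genes moved the same way in all 4 mice, which their choice among called genes favours. The widest spread among CD117pos arrays is that of Egr1, from 18.3 in mouse _951 to 526.7 in mouse _948. The Egr1 call ended without mouse _953 (adjusted p = 0.0796).

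Hoxa9, a homeobox gene that MLL fusions activate, measured 5516 ± 414 and 5446 ± 496, a log2 difference of -0.02 ± 0.10 (adjusted p = 0.919). Its partner Meis1 measured 1779 ± 220 and 1536 ± 242, a difference of -0.21 ± 0.11 (adjusted p = 0.238), and Hoxa10 993 ± 184 and 1116 ± 188. These 3 genes were chosen after their values were seen. Of 20 listed targets of MLL fusions, 1 rose and 4 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.41). The 4 falls became 1 after quantile normalisation and with a pseudocount of 1, 2 after centring, and 1, 4, 1 and 0 without mice _948, _951, _952 and _953 in turn. The 1 rise became 0 with a pseudocount of 1 and without mouse _948, _952 or _953, and there were 2 rises with the mean of probe sets. The target with the largest fall was Cpeb2, an mRNA-binding protein gene, from 716 ± 169 to 109 ± 55.8, a call that ended without mouse _953 (adjusted p = 0.0565). Its difference was -1.54 with the mean of probe sets and -2.78 without mouse _953, against -2.69.

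Regulators of stem and progenitor cells mostly did not pass the test. Of 26 measured, 4 rose and 1 fell, also when adjusted over the list alone, with a camera adjusted p of 0.283 and 0.0376 by fry. Without mice _948, _951, _952 and _953 in turn, 1, 6, 3 and 2 rose. The 1 fall became 0 without mouse _948 and 2 without mouse _951. Myc went from 203 ± 32.7 to 494 ± 41.7, a log2 difference of 1.23 ± 0.15, and Prom1, the CD133 gene, from 1189 ± 269 to 2265 ± 472, a call that ended without mouse _948 (adjusted p = 0.0507). The 3 genes made prominent by work on MLL leukaemia stem cells formed their own list. Hmgb3, a high mobility group protein gene, went from 292 ± 30.4 to 961 ± 101, a log2 difference of 1.66 ± 0.13. Cbx5, encoding heterochromatin protein HP1α, went from 392 ± 52.0 to 833 ± 182, a difference of 1.04 ± 0.18. Myb measured 5226 ± 212 and 6402 ± 436, a difference of 0.29 ± 0.11 that did not pass the threshold (adjusted p = 0.131), but did after quantile normalisation (0.0401), with a pseudocount of 64 (0.0395), with the mean of probe sets (0.0241) and with an intensity trend (0.0321). The Cbx5 call ended without mouse _948 (adjusted p = 0.0725), _952 (0.056) and _953 (0.0645), with differences of 0.95, 1.09 and 0.91. Without mouse _951 the Cbx5 call held (adjusted p = 0.00418). The list had 2 rises and 0 falls (3 and 0 when adjusted over the list alone), a median of 1.04 and a camera adjusted p of 0.0068, with adjusted p = 0.269 under an estimated correlation. As this list may have been chosen on these samples, it is no independent evidence of its direction.

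Chromatin regulators went both ways. Of 17 genes of heterochromatin and DNA methylation, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.19). The histone methyltransferase gene Suv39h2 went from 58.6 ± 24.1 to 158 ± 36.7. The call ended without mouse _953 (adjusted p = 0.0622), with a log2 difference of 1.23 against 1.28 over all mice. Of 30 polycomb and trithorax genes, 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.59). The polycomb gene Phc2 went from 1011 ± 232 to 388 ± 217, and Psip1, whose product LEDGF binds MLL, from 345 ± 86.2 to 605 ± 119. After quantile normalisation 5 rose and 1 fell in each of these lists. Without mice _948, _952 and _953 in turn, 1, 1 and 0 heterochromatin genes rose and 0 fell, and each time 1 polycomb or trithorax gene rose and 1 fell.

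Marker lists of 9 other cell types did not pass camera, with adjusted p from 0.0682 to 0.839, and a few single markers moved. Fry, which does not set a list against other genes, called the megakaryocyte (adjusted p = 0.0196), stromal (0.0363) and B cell lists (0.0401) as lower and the erythroid list (0.0433) as higher. The 12 megakaryocyte and platelet genes had the lowest adjusted p, with 4 falls and 0 rises, also when adjusted over the list alone. Camera called them after quantile normalisation (adjusted p = 0.0328), with a pseudocount of 1 (0.0468) and without mouse _948 (0.0291). Without mice _948, _952 and _953 in turn 1 of them fell. Their largest fall was Thbs1, from 1005 ± 364 to 41.1 ± 22.4, a gene that macrophages also express. In the mast cell and basophil list, Mcpt8 alone rose, from 72.2 ± 38.9 to 278 ± 168. None of 7 eosinophil genes passed, and the largest difference among them was that of Epx, 0.29 ± 0.17. Of 16 erythroid genes 2 rose and 0 fell, Tfrc, the transferrin receptor gene of dividing cells, from 1416 ± 182 to 3160 ± 664, and Rhd, whose call ended without mouse _948 (adjusted p = 0.0968), _952 (0.119) and _953 (0.119), with a pseudocount of 1 (0.0543) and with an intensity trend (0.0542). Of 17 T cell genes Cd28 fell, by 1.60 on the log2 scale, a call that ended without the block (adjusted p = 0.0861) and without it and the CD117pos array of mouse _951 (0.0604). Of 14 B cell genes, Cd22 fell from 326 ± 97.9 to 17.2 ± 5.92. Ighm fell as well, by 0.77, with a call that ended without the block (adjusted p = 0.104), without mouse _948 (0.159), _951 (0.063) and _953 (0.144), after quantile normalisation (0.0774) and centring (0.0541), with a pseudocount of 1 (0.0756) and with the mean of probe sets (0.406). Of 11 NK cell genes Klra8 rose, from 7.72 ± 5.93 to 19.3 ± 9.77, near the floor of the arrays, and the call ended without the block (adjusted p = 0.138) and without mouse _948 (0.0879), _952 (0.0885) and _953 (0.0622). Of 12 dendritic cell genes Ly75 fell, from 1263 ± 95.6 to 296 ± 175, and the call ended without mouse _948 (adjusted p = 0.0848) and _953 (0.07). Of 20 stromal and endothelial genes 4 fell and 1 rose (7 and 2 when adjusted over the list alone; 2 falls and 0 rises without mouse _948, _952 or _953 and 7 falls without _951), Cxcl12 from 629 ± 383 to 21.5 ± 20.3. The rise, that of Vcam1, also became 0 rises with pseudocounts of 1 and 64, with the mean of probe sets and without the CD117pos array of mouse _951 and the block. Of 4 sex-linked genes 0 passed, the largest difference being that of Eif2s3y, -0.34 ± 0.13, with a call without mouse _951 (adjusted p = 0.0336). Adjusting over each list alone changed none of the other counts of this paragraph except that of the B cell list, which became 1 fall.

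Between the 4 mice, 0 of 18193 genes passed the threshold in limma's moderated F-test, while 1403 had an unadjusted p under 0.05, and no other tool was run. The 5 genes with the largest F were Car3, Grk3, Sdk1, Cfb and A930004D18Rik. The carbonic anhydrase gene Car3 measured 251.2 and 896.8 in the CD117neg and CD117pos arrays of mouse _951, against 14.4 to 49.6 and 78.1 to 154.3 in the other mice (adjusted p = 0.149 between mice). Grk3, a receptor kinase gene, measured 208.8 and 27.8 in mouse _951, against 1024 to 1354.4 and 217.3 to 318 in the other mice (adjusted p = 0.182).

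Of 9 control measures of the arrays, 0 passed the threshold between fractions, and 1 array stood apart. Signals of dap and thr, bacterial polyA transcripts supplied to be added to RNA before labelling, were lower in CD117pos arrays. The dap signal was 401 ± 61.8 in CD117neg and 85.2 ± 46.3 in CD117pos arrays, a log2 difference of -2.48, or -1.85 without mouse _951 (two-sided exact permutation within mice, p = 0.125 for all 4 mice, adjusted p = 0.188), lower in all 4 mice. The signal of cre, a control added at hybridisation, differed by -0.20 (exact permutation p = 0.125, adjusted p = 0.188). The 18S ribosomal RNA signal was 3960 ± 374 and 1910 ± 501 (exact permutation p = 0.125, adjusted p = 0.188). With 4 pairs, the smallest p that this test allows is 0.125, so it could not pass the threshold. The CD117pos array of mouse _951 had a ratio of 3′ to 5′ Gapdh signal of 5.44, against 2.56 to 3.23 in the other 7 arrays, and 2538 genes over 2-fold from the mean of the other CD117pos arrays, against 121 to 590 genes for every other array within its fraction.

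**Figure D4:**
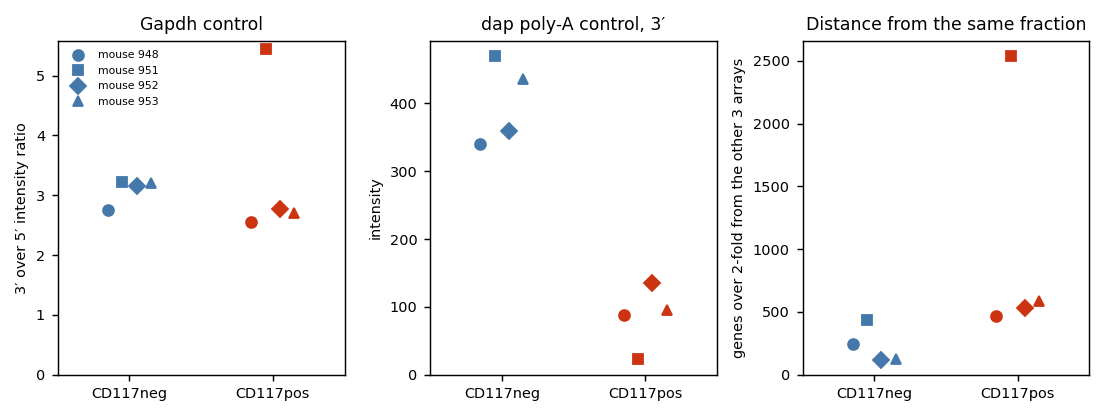
The panels show 3 measures per array, with CD117neg arrays in blue, CD117pos arrays in red and a symbol per mouse: the ratio of 3′ to 5′ Gapdh intensity, the intensity of the dap control, and the number of genes over 2-fold from the mean of the other 3 arrays of the fraction. The CD117pos array of mouse _951 has the highest ratio (5.44), the lowest dap intensity (23.2) and the most genes apart (2538).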

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

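Each test of why the CD117pos array of mouse _951 differed was chosen after the result was seen. Of 255 groups of 4 values examined, 26 held 1 value far from the others by Dixon's criterion, where chance gives about 1 in 20 for independent groups. The groups share arrays and include the genes chosen for the largest F between mice, so this is no test against chance. Of the 26, 10 lay in the CD117pos array of mouse _951.

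In that array, the cathepsin gene Ctsh measured 55.4 against 762.3 to 1026.7 in the other CD117pos arrays, and the MLL fusion target Cpeb2 28.5 against 125.3 to 157. Ccl6 measured 53.1 against 101.5 to 112.1, Tfe3 58.2 against 149.3 to 168.5, Dusp1 182.4 against 318.2 to 335.5 and Aldoc 24.9 against 62.9 to 71.8. Ndufa5 was higher, at 2555.3 against 1315.4 to 1455.8. A930004D18Rik measured 3.9 against 250.2 to 358.8. The array's ratio of 3′ to 5′ signal was 5.44 against 2.56 to 2.77 for Gapdh and 3.21 against 1.72 to 1.91 for actin.

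In the CD117neg array of mouse _951, Nkg7 measured 152.9 against 10.7 to 20.5 in the other CD117neg arrays, and Itgb3 57.1 against 12.5 to 17.1. Clec4n measured 869.7 against 2718.9 to 3330, Cd74 321.6 against 991.5 to 1110.2 and Nr4a1 630.8 against 1886.6 to 2185.1. Grk3 measured 208.8 against 1024 to 1354.4, and A930004D18Rik 29 against 277.2 to 407.6. Between the fractions of mouse _951, median log2 differences were -3.73 for late neutrophil genes against -2.15 to -1.95 in the other mice, -1 for p53 targets and apoptosis against -0.74 to -0.72, and -0.65 for glycolysis against -0.27 to -0.22.

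Among other arrays, Cxcr2 measured 31.5 in the CD117pos array of mouse _952 against 4.4 to 4.9, and Mrpl50 868.2 in that of mouse _953 against 646 to 668.5. Cenph measured 129.2 in the CD117neg array of mouse _952 against 72 to 79.9, and Suv39h2 22.9 in that of mouse _948 against 66.8 to 75.3. The Gapdh ratio of the CD117neg array of mouse _948 was 2.76 against 3.16 to 3.23. The median log2 difference of the dendritic cell list was -0.08 in mouse _953 against -0.03 to -0.02. Of 10092 probe sets left out of the gene tests, 932 with several genes and 9160 with none listed, 1116 passed the threshold (limma, adjusted p under 0.05), 255 higher and 861 lower in CD117pos.

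The CD117pos array of mouse _951 lay over 2-fold above the mean of the other CD117pos arrays, and above each of them, in 1471 genes and as far below in 1058, such as Satb1 (1111.7 against 3.2 ± 0.488), Klf9 (2883.2 against 70.5 ± 33.7) and Cybb (41.2 against 834.6 ± 315). Loss of RNA lowers signals, whereas 127 genes lay at least 8-fold above each other CD117pos array, where those arrays had 0 to 2 such genes. This argues against a loss without later scaling for the raised genes. The scaling between arrays is not given, so signals relative to other arrays may rise after a loss, and RNA quality stays open for these genes. Admixture of cells other than leukaemia cells is argued against for the lowered genes, whose median deviation was -1.35 on the log2 scale, by 17 MLL fusion targets of moderate or high intensity, whose median of 0.17 lies above that by more than their SD of 1.03, although 2 of them were lowered and the admixed cells may express some. These targets cannot test a different share of CD117neg leukaemia cells, because their list did not pass camera between the fractions. Of erythroid, mast cell and T cell markers 25%, 20% and 17.6% were raised, against 8.09% of all genes, too few markers to decide, so admixed cells stay open for the raised genes. The CD117neg array of mouse _951 was the highest of 4 in 40.1% of the raised genes, against 12 to 24.3% for the other CD117neg arrays. It was the lowest of 4 in 44% of the lowered genes, against 13.2 to 27.1%. Each other mouse's own CD117neg array was so in 46.2 to 50% and 21.5 to 48.1% of that mouse's own raised and lowered genes. Such sharing is thus not particular to mouse _951 and does not decide on a leukaemia cell state of this mouse. That state stays open and cannot be told apart from RNA loss.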

How the results depend on the processing

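One alternative, without the CD117pos array of mouse _951 and without the block, was chosen after the data were seen. Kit stayed higher and past the threshold under every alternative in which it was fitted, with 4.05 to 4.23 on the log2 scale when a mouse was left out, 2.61 with the mean of its probe sets, 3.13 with a pseudocount of 64 and 4.72 with one of 1. Genes higher in CD117pos numbered 1521 and genes lower 2518. These became 2439 and 1941 after quantile normalisation, 1004 and 1874 with a pseudocount of 1, and 403 and 1331 when a change of at least 2-fold was asked for. Why the pseudocount of 1 lowered the counts was not tested. Leaving out a mouse gave 440 to 2130 higher and 1219 to 2985 lower genes. Both counts were lowest without mouse _953 and highest without mouse _951, and 3 mice give less power than 4. Under the other settings 1485 to 2167 genes were higher and 2084 to 2955 lower. No gene passed the threshold between mice in any fit with the block (0 in each, limma, with 1403 at an unadjusted p under 0.05 over all 4 mice). Over all 4 mice this test rested on 3 residual degrees of freedom, so it does not show that the mice were alike.

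The block was left out as an alternative to the pairing by mouse. This gave 1525 higher and 2540 lower genes, of which 1304 and 2279 were shared with the blocked calls, and 18 lists against 17. Without it, the calls of 9 of 105 named genes ended, among them those of Pbx3 (adjusted p = 0.188), Angpt1 (0.173), Itgb3 (0.292), Vcam1 (0.0867), Car3 (0.258) and Grk3 (0.0706). The cytosolic ribosomal protein list gained a call (0.0274).

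With an estimated correlation, 0 of 33 lists passed camera (6 had an unadjusted p under 0.05), against 17 at the preset value. The estimated correlation was -0.0118 for MHC class II presentation, below the preset 0.01, yet its camera adjusted p went from 0.000108 to 0.206. A higher correlation within this list thus cannot account for that rise. The adjusted p also depends on the p-values of the other lists, such as mitosis with an estimated correlation of 0.815. What ended the call of the MHC class II list therefore stays open. With an estimated correlation, camera takes its degrees of freedom from the residuals of the fit, here 3, which leaves little power. Which lists lost their call through correlation was not tested. Fry, which does not set a list against other genes, called 22. Counts of changed members within lists moved with the mouse left out and are given beside many of the lists. Without a mouse 17 to 19 lists passed, as under the other settings. Without probe sets of shared sequence, Acta2 was represented by another probe set and differed by 0.36 (adjusted p = 0.41), against -1.05 with its brightest probe set. The Acta2 call also ended with the mean of its probe sets (adjusted p = 0.648). Calls of named genes ended for 25 without mouse _948, 2 without _951, 20 without _952 and 29 without _953. They ended for 10 with a pseudocount of 1, 11 with the mean of probe sets, 4 with a pseudocount of 64, 4, Acta2 included, without probe sets of shared sequence, 3 each after quantile normalisation and centring, 1 with an intensity trend and 8 without the CD117pos array of mouse _951. No call of a named gene ended with a robust prior, or for the 101 named genes among the 10916 left without low ones. A call could end with little change in the difference, as for Egr1, at -3.04 without mouse _953 against -3.10 over all mice. For Vcam1 the difference moved more, to 0.96 without mouse _952 against 1.30. Signal near the floor limits what can be read of genes of low intensity.

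The number of calls was set against other assignments of the fractions. With the block, the real assignment gave 4039 genes and the highest other 0, and 17 lists against 12. There are 8 such assignments, of which 1 gave as many in each case, too few for a share under 0.05. Without the block, 1 of 35 splits of the arrays gave as many genes, the real one with 4065, and the highest other gave 1. Chance can be excluded for that count only against splits that ignore the pairs by mouse, since the splits that part every pair are the 8 assignments above.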

Other observations

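Every test in this part was chosen after the data were seen. Genes whose symbols share a stem were grouped into 311 families of at least 8 measured members, and the calls of each family were set against all genes (one-sided Fisher's exact test, adjusted over the families), with genes that are not independent replicates. Rises were enriched in 13 families and falls in 14. Among rises, 7 of 10 Exosc genes, which encode the RNA exosome, were higher in CD117pos cells and 0 were lower (adjusted p = 0.000559), Exosc7 going from 753 ± 141 to 1937 ± 417. Of 15 Timm genes, for import of proteins into mitochondria, 8 rose and 0 fell (adjusted p = 0.000916), Timm9 going from 64.9 ± 12.3 to 177 ± 13.9. Of 8 Ndufaf genes, which encode assembly factors of respiratory complex I, 5 rose and 0 fell (adjusted p = 0.00877), and Ndufaf6 went from 60.8 ± 12.6 to 179 ± 42.7. Of 37 genes with the stem Cep, most of them for centrosomal proteins but the opposite-strand transcript Cep83os among the rises, 13 rose and 1 fell (adjusted p = 0.00076), and of 16 Rad genes, many of them for DNA repair, 8 rose and 1 fell (0.00127). Cep97 went from 135 ± 44.6 to 402 ± 174 and Rad51ap1 from 679 ± 154 to 1393 ± 117. After quantile normalisation 7 Exosc, 10 Timm, 5 Ndufaf, 16 Cep and 8 Rad genes rose.

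Among falls, 11 of 16 Dennd genes, which encode exchange factors of Rab GTPases, were lower in CD117pos cells and 0 were higher (adjusted p = 0.000469), Dennd3 going from 429 ± 138 to 34.8 ± 8.52. Of 72 Rab genes, for these GTPases and their partners, 25 fell and 0 rose (adjusted p = 0.000776), while 13 fell and 3 rose after quantile normalisation. Rab19 went from 131 ± 28.2 to 16.3 ± 3.46. Of 8 Csf genes, for colony-stimulating factors and their receptors, 6 fell and 0 rose (adjusted p = 0.0085), and Csf1r, the receptor gene of macrophage growth factor, went from 7600 ± 1018 to 920 ± 603. Of 15 Pik genes, mostly of phosphoinositide 3-kinases, 8 fell and 0 rose (adjusted p = 0.0134), and of 9 Rap genes, for Ras-related GTPases and related proteins, 6 fell and 0 rose (0.0147). Pik3r5 went from 804 ± 41.1 to 93.4 ± 57.7 and Rap1gap2 from 2417 ± 304 to 164 ± 88.8. After quantile normalisation 10 Dennd, 4 Csf, 6 Pik and 5 Rap genes fell, and 1 Pik and 1 Rap gene rose. The 6 falls among 8 Kmt genes of histone methyltransferases (adjusted p = 0.0085) became 2 after quantile normalisation and 3 after centring.

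More genes were lower than higher in CD117pos in the intensities as deposited, but fewer after quantile normalisation, so array-wide scaling may account for this balance over all calls. Among calls of under 2-fold, quantile normalisation raised the share of higher genes from 48.5% to 66.6%, by 18.1 percentage points, so that direction is open for these calls as a whole. Among calls of at least 2-fold it raised the share from 23.2% to 40.2%, by 17.0 points, so scaling may account for part of the balance there as well. After it 1084 genes were still lower against 729 higher, and after centring 1171 against 570, so neither removed this excess of falls. Whether another scaling would was not tested. The deposited scaling is not given in the sources used here, and quantile normalisation assumes 1 distribution for both fractions, so a true excess of falls stays open.

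The polyA control dap was 3.89, 20.3, 2.66 and 4.58 times lower in the CD117pos than in the CD117neg array of mice _948, _951, _952 and _953, and thr 4.93, 12.1, 2.31 and 4.02 times lower. The geometric mean fold was 5.58 for dap and 4.86 for thr, and 3.62 and 3.58 without mouse _951. The hybridisation control cre was 1.04 to 1.21 times lower.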
